A study of Homo sapiens with 6 samples.

How the data were processed

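ChIP-seq was done on Kasumi-1 cells with antibodies C19 and N20 against AML1 and with an antibody against ETO, and on U937 cells with C19. Total input DNA of each cell line was the control, per the labels. The 4 antibody libraries had a peak list each, and the 2 input libraries had no file used here. The submitters' processing notes name the aligner BWA 0.7.7, the peak caller MACS 1.4.2 and the build hg19, without their settings. Each deposited list has 3 columns, the chromosome, start and end of each peak, with no peak score, summit, fold or p-value. Peaks were listed per library, so replicates were not pooled, and filters or excluded regions are not given in the sources used here. The file names carry 1e-8 for C19, ETO and U937 and 1e-5 for N20, read here as the p threshold of peak calling. A more permissive threshold lengthens a list and raises the share of other lists that it overlaps. Peaks of one list did not overlap one another, and no list had peaks on chromosome Y.

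Because peaks without scores, reads or replicates cannot carry a test between conditions, no p-value is given. Shares of peaks have 95% Wilson intervals, and differences between shares have Newcombe intervals. They cover counting error only and treat peaks as independent, which neighbouring peaks are not. Peaks of different lists were called overlapping when they shared at least 1 bp. The 2 directions of an overlap differ slightly in number because 1 peak can overlap 2. Chance levels came from 1000 random placements of the peaks of one list within the span that peaks of any list covered on their chromosome, and from 200 rounds in which each peak was moved by 5 to 50 kb to either side. Neither excludes assembly gaps or unmappable sequence. Merged Kasumi-1 sites are the union of the overlapping peaks of the 3 lists. Peak width stood in for the missing score, a choice made after the form of the lists was seen, with the limit that width also depends on fragment length, local copy number and threshold. Medians of widths and Spearman correlations have bootstrap intervals over peaks, from 1000 and 200 draws. Paired widths are those of each C19 peak and the AML1/ETO peak with the largest overlap. Coordinates are 1-based.

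Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The overlap code was tested on simulated lists of 15374 peaks: for planted shares of 10%, 40% and 75% and their chance overlaps, expected to give 11.02%, 40.7% and 75.28%, it returned 11.03%, 40.71% and 75.32%. The width-standardised difference was tested on 24154 simulated peaks in which width alone drove both features: the raw difference was 4.07 percentage points and the standardised one 0.0964, and the interval held 0 in 91 of 100 runs.

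The comparisons, the overlap definitions and gene lists were fixed before the data were examined. Several planned parts could not be run on lists of this form: the stricter threshold of 1e-10, the 3000 highest-scoring peaks, N20 at 1e-8 and the correlation of scores all need a score. Motif content, promoter shares and the fixed gene lists, and the rule that named the highest-scoring sites of each class by their nearest gene, were not analysed here, because the gene table at hand is on GRCh38 and coordinates were not carried between builds. In their place, peaks were ranked by width, the 3 widest sites of each class and the 3 densest 1 Mb windows of each list were examined, and the widest or densest are described. The alternatives tried were an overlap of at least 50% of the shorter peak, peak centres within 250 bp, leaving out chromosome X, the 3000 widest peaks of every list, standardising over deciles of width, keeping N20-supported peaks only, and leaving out a stretch of chromosome 4 with wide peaks.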

Results

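Binding sites of AML1 and of the fusion protein AML1/ETO were mapped by ChIP-seq, in which DNA fragments bound by a protein are pulled down with an antibody and sequenced. AML1, also called RUNX1, is a DNA-binding transcription factor of blood cell development. AML1/ETO joins its DNA-binding part to the corepressor-binding protein ETO (RUNX1T1) and arises from the t(8;21) translocation of acute myeloid leukaemia. Kasumi-1 is a leukaemia cell line that carries this translocation and makes both proteins. In Kasumi-1, antibody C19 was raised against the end of AML1 that the fusion lacks and so detects AML1 alone. The ETO antibody detects AML1/ETO, and antibody N20 detects the N-terminal part that both proteins share. AML1 was also mapped with C19 in U937, a human myeloid cell line that the labels describe as macrophage and that served as the cell line other than Kasumi-1. The series held 6 samples, 4 from Kasumi-1 and 2 from U937, of which 2 were total input DNA. Each antibody and cell line was represented by 1 library, so no comparison below has a replicate check. The files held 1 peak list per antibody library, with positions on hg19 but no peak heights, read numbers or p-values, and sequencing depth is therefore unknown. Intervals in brackets are 95% intervals of a share of peaks and cover counting error only.

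The C19 list held 24154 AML1 peaks, the N20 list 24007 peaks and the AML1/ETO list 15374 peaks in Kasumi-1. The U937 list held 9827 AML1 peaks. Peaks were narrow in Kasumi-1, with a median width of 549 bp for C19, 662 bp for N20 and 520 bp for AML1/ETO, and wider in U937, with a median of 802 bp. The lists covered 14.7 Mb, 18.7 Mb, 9.31 Mb and 8.84 Mb of the genome in the same order. The value in the name of each list, read here as its peak-calling p threshold, was 1e-5 for N20 and 1e-8 for the other lists, so the N20 list was called at a more permissive setting.

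The first comparison asked how far AML1/ETO and AML1 occupy the same places in the leukaemia cells. Most AML1/ETO peaks lay on an AML1 peak: 11660 of 15374, or 75.8% (75.2 to 76.5), overlapped a C19 peak by at least 1 bp. The reverse share was lower, with 11656 of 24154 AML1 peaks, or 48.3% (47.6 to 48.9), overlapping an AML1/ETO peak. Thus 12498 AML1 peaks had no AML1/ETO peak and 3714 AML1/ETO peaks had no AML1 peak. After peaks were placed at random on their chromosomes 1000 times, the mean share of AML1/ETO peaks on a C19 peak was 1.15%, and the highest was 1.45%. Moving each peak by 5 to 50 kb, which keeps the regional density, gave a mean of 3.28% and a highest value of 3.66% over 200 draws. The observed share was 65.8 times the first of these levels and 23.1 times the second. Both lists come from the same cell line, and regions that collect reads with any antibody are not part of these chance levels. Among the 3000 widest peaks of each list the share of AML1/ETO peaks on an AML1 peak was 46.9%, the same as the reverse share. Lists of equal length give about equal shares in both directions. The cut also removes narrower peaks that could be overlapped, so this share does not show that wide peaks overlap less.

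Shared sites carried wider peaks. The median AML1 peak was 610 bp wide with an AML1/ETO peak and 499 bp without, a difference of 111 bp (105 to 116, bootstrap over peaks). AML1/ETO peaks had a median width of 550 bp with an AML1 peak and 451 bp without, a difference of 99.0 bp (92.5 to 107). The share of AML1/ETO peaks on an AML1 peak was 60.6% (58.1 to 63.0) in the narrowest decile, of median width 291 bp, and 93.3% (91.9 to 94.4) in the widest, of median width 1208 bp. For AML1 peaks the share with AML1/ETO was 22.4% (20.8 to 24.1) in the narrowest decile and 73.6% (71.8 to 75.3) in the widest. At the 11656 AML1 peaks with an AML1/ETO peak, the centres of the overlapping peaks were a median of 50 bp apart, and 93.4% were within 250 bp. The widths of the paired peaks were correlated across sites, with a Spearman rho of 0.59 (0.58 to 0.61, bootstrap). Sites are not independent replicates, and a wider peak also has more bases that can be overlapped.

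Antibody N20 was used to tell how well each specific antibody's sites were recovered by an antibody that detects both proteins. N20 recovered nearly all AML1/ETO sites and a smaller share of AML1 sites. Of the AML1/ETO peaks, 94.6% (94.26 to 94.97) overlapped an N20 peak, and of the C19 peaks 67.0% (66.4 to 67.6) did. Mean chance shares after random placement were 1.30% and 1.28%, and after moving peaks by 5 to 50 kb they were 4.10% and 3.43%. AML1 peaks that also had AML1/ETO were found by N20 in 97.7% of cases (97.4 to 98.0), and AML1 peaks without it in 38.4% (37.5 to 39.2). AML1/ETO peaks without a C19 peak overlapped N20 in 85.2% of cases (84.0 to 86.3). Among the 3000 widest peaks of each list, 20.6% (18.7 to 22.7) of AML1 peaks without AML1/ETO lay on N20. For AML1/ETO peaks without C19 the share was 51.6% (49.2 to 54.1). Every list is cut there, N20 included, so a peak counted as without another can overlap a narrower one. The cut alone thus lowers these shares. In the full lists, N20 overlapped 99.6% of the widest decile of AML1/ETO peaks and 84.6% of the widest decile of C19 peaks. Seen from N20, 46.3% of its peaks overlapped both other lists, 19.4% C19 but not AML1/ETO, 12.3% AML1/ETO but not C19 and 22.0% neither.

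Merging overlapping peaks gave 32338 Kasumi-1 sites. All 3 antibodies marked 11033 sites, or 34.1% (33.6 to 34.6). N20 with C19 but not AML1/ETO marked 4596 sites (14.2%), and N20 with AML1/ETO but not C19 marked 2902 sites (8.97%). The C19 antibody alone marked 7704 sites (23.8%), N20 alone 5288 (16.4%) and the ETO antibody alone 550 (1.70%). C19 with AML1/ETO but no N20 marked 265 sites (0.819%). Sites marked by all 3 antibodies had a median merged width of 877 bp, against 486 bp for C19 alone and 379 bp for AML1/ETO alone. A merged site spans all its peaks, so a site of more lists tends to be wider by construction. The C19 peaks themselves had a median width of 613 bp with both AML1/ETO and N20, and 486 bp with neither.

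**Figure D1:**
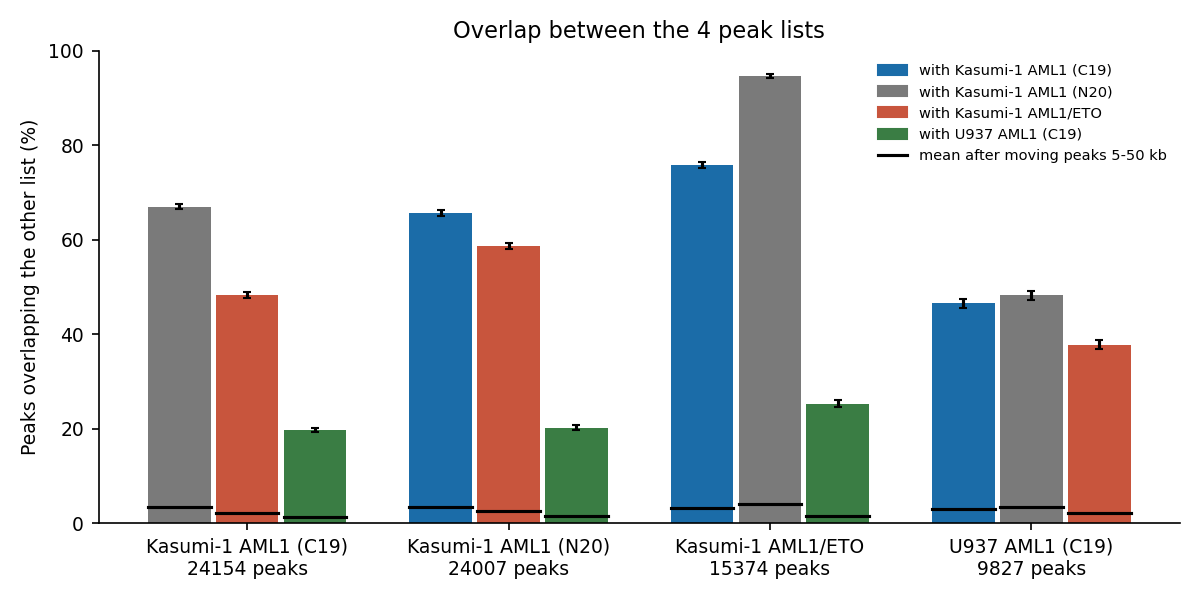
Share of the peaks of each list (groups on the x axis) that overlap each other list by at least 1 bp (bars, in %, with 95% Wilson intervals), and the mean share after peaks were moved by 5 to 50 kb (black lines). The AML1/ETO list overlaps N20 in 94.6% and C19 in 75.8% of its peaks, while overlap with the U937 list reaches at most 25.3% in any Kasumi-1 list.

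The second comparison set AML1 binding in Kasumi-1 against AML1 binding in U937, with the same antibody. Fewer than 50% of the U937 sites were also AML1 sites in Kasumi-1, and most of those shared sites also had an AML1/ETO peak. Of the U937 peaks, 46.6% (45.6 to 47.6) overlapped a Kasumi-1 C19 peak, 48.2% (47.3 to 49.2) an N20 peak and 37.8% (36.8 to 38.7) an AML1/ETO peak. No Kasumi-1 peak of any list lay on 45.0% (44.1 to 46.0) of them. In the other direction, 19.7% (19.2 to 20.2) of the longer Kasumi-1 C19 list overlapped a U937 peak. These shares were 35.8 and 36.6 times the chance level of random placement, and 16.1 and 16.3 times that of moving peaks by 5 to 50 kb. U937 peaks with a Kasumi-1 AML1 peak had a median width of 870 bp, against 755 bp for those without, and the share with one went from 31.8% in the narrowest decile to 64.1% in the widest. Among the 3000 widest peaks of each list, the order turned: 19.1% of U937 peaks overlapped a Kasumi-1 C19 peak and 23.1% an AML1/ETO peak. The full C19 list is longer than the AML1/ETO list, at 24154 against 15374 peaks. Relative to chance, the full U937 list already overlapped AML1/ETO more, at 45.7 times random placement and 17.5 times moved peaks. The ranges of these folds over the draws overlapped those for C19.

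AML1 sites that also held AML1/ETO in Kasumi-1 were found in U937 more often than AML1 sites without the fusion protein. Of the Kasumi-1 AML1 peaks with an AML1/ETO peak, 29.3% (28.5 to 30.1) overlapped a U937 AML1 peak, and of those without, 10.8% (10.2 to 11.3) did. The difference was 18.6 percentage points (17.6 to 19.5). It was present in each quartile of AML1 peak width, at 10.7 points (8.56 to 12.9) among the narrowest peaks, 14.8 and 19.8 points in the middle quartiles and 24.2 points (22.2 to 26.1) among the widest. Over these quartiles the share rose from 21.6% to 33.5% for AML1 peaks with AML1/ETO, and lay between 9.32% and 11.6% for those without. AML1/ETO peaks without a C19 peak overlapped U937 AML1 in 13.0% of cases (11.9 to 14.1). Seen from U937, 72.0% (70.7 to 73.3) of its peaks on a Kasumi-1 AML1 peak also lay on an AML1/ETO peak, against 7.92% (7.22 to 8.68) of its other peaks, while 48.3% of all Kasumi-1 AML1 peaks did. The share of its other peaks was 12.2% (10.9 to 13.5) among the 3000 widest peaks of each list. There, the other peaks are those that overlap none of the 3000 widest C19 peaks, and they can overlap a narrower one.

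**Figure D2:**
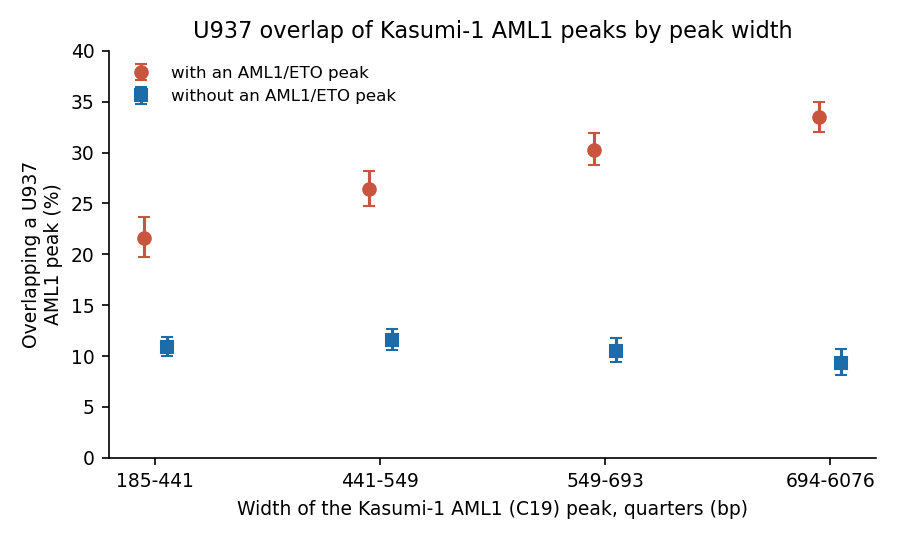
Share of Kasumi-1 AML1 (C19) peaks that overlap a U937 AML1 peak (y axis, %), by quartile of C19 peak width in bp (x axis), for peaks with (circles) and without (squares) an AML1/ETO peak, with 95% Wilson intervals. The share goes from 21.6% to 33.5% with AML1/ETO and stays between 9.32% and 11.6% without.

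Among the merged Kasumi-1 sites, overlap with U937 AML1 was highest where all 3 antibodies had marked the site, at 29.7% (28.8 to 30.5). It was 15.5% (14.5 to 16.6) for sites of C19 and N20, 13.4% (12.2 to 14.7) for sites of N20 and AML1/ETO, and 14.7% (10.96 to 19.49) for the few sites of C19 and AML1/ETO. Sites marked by 1 antibody overlapped U937 least. The shares were 7.93% (7.35 to 8.56) for C19, 8.47% (7.75 to 9.25) for N20 and 8.91% (6.80 to 11.6) for AML1/ETO, with intervals that overlap one another. Merged sites of more lists tend to be wider by construction and have more bases that can be overlapped. Unmerged C19 peaks gave similar shares: 29.7% with N20 and AML1/ETO, 15.3% with N20 but not AML1/ETO, and 7.93% with neither.

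**Figure D3:**
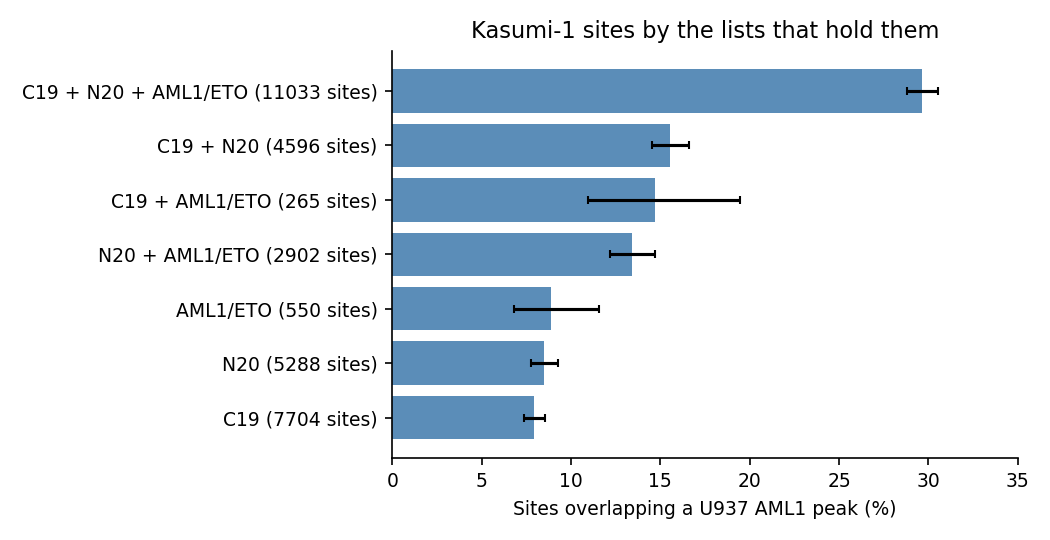
Share of merged Kasumi-1 sites that overlap a U937 AML1 peak (x axis, %), for each combination of the lists that hold the site (y axis, number of sites in brackets), with 95% Wilson intervals. Sites of all 3 antibodies reach 29.7%, and sites of a single antibody lie between 7.93% and 8.91%.

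AML1/ETO peaks without a C19 peak lay near a C19 peak more often than randomly placed peaks did. Of the 3714 AML1/ETO peaks without an overlapping C19 peak, 47.1% (45.5 to 48.7) had a C19 peak centre within 10 kb, and their median distance to the nearest one was 11.3 kb. Random placement gave a mean of 14.1% and a highest value of 15.9% over 1000 shuffles. Of the 12498 AML1 peaks without AML1/ETO, 22.4% (21.6 to 23.1) had an AML1/ETO peak centre within 10 kb, against 8.92% at random, with a median distance of 38.0 kb. The lists differ in length, so these shares are to be read against their own chance levels, which leave out the clustering of the peaks.

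As the lists carry no score, individual sites were picked by width, after their values were seen, and are given by hg19 position without a gene name or annotation. The widest AML1 peak shared with AML1/ETO covered 6076 bp at chromosome 4, 55522794 to 55528869. It also had an N20 peak but no U937 peak. The widest AML1 peak without AML1/ETO, 4057 bp, lay near it at chromosome 4, 55573357 to 55577413, and was found by N20 too. The widest AML1/ETO peak without C19, 1837 bp at chromosome 17, 48547169 to 48549005, overlapped an N20 peak and no U937 peak. In U937 the widest peak, 4955 bp at chromosome 18, 60101653 to 60106607, overlapped no Kasumi-1 peak. The next widest, 4494 bp at chromosome 18, 60764467 to 60768960, overlapped peaks of all 3 Kasumi-1 lists.

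Both chromosome 4 sites lay in a stretch from 54774554 to 55686558 in which Kasumi-1 peaks were wide. It held 26 C19 peaks of 807 to 6076 bp, 16 N20 peaks of 1247 to 8782 bp and 16 AML1/ETO peaks of 584 to 3823 bp, each of them wider than the median of its list. Its 5 U937 peaks were 523 to 1194 bp wide, against a U937 median of 802 bp. All 5 overlapped a Kasumi-1 C19 peak.

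**Figure D4:**
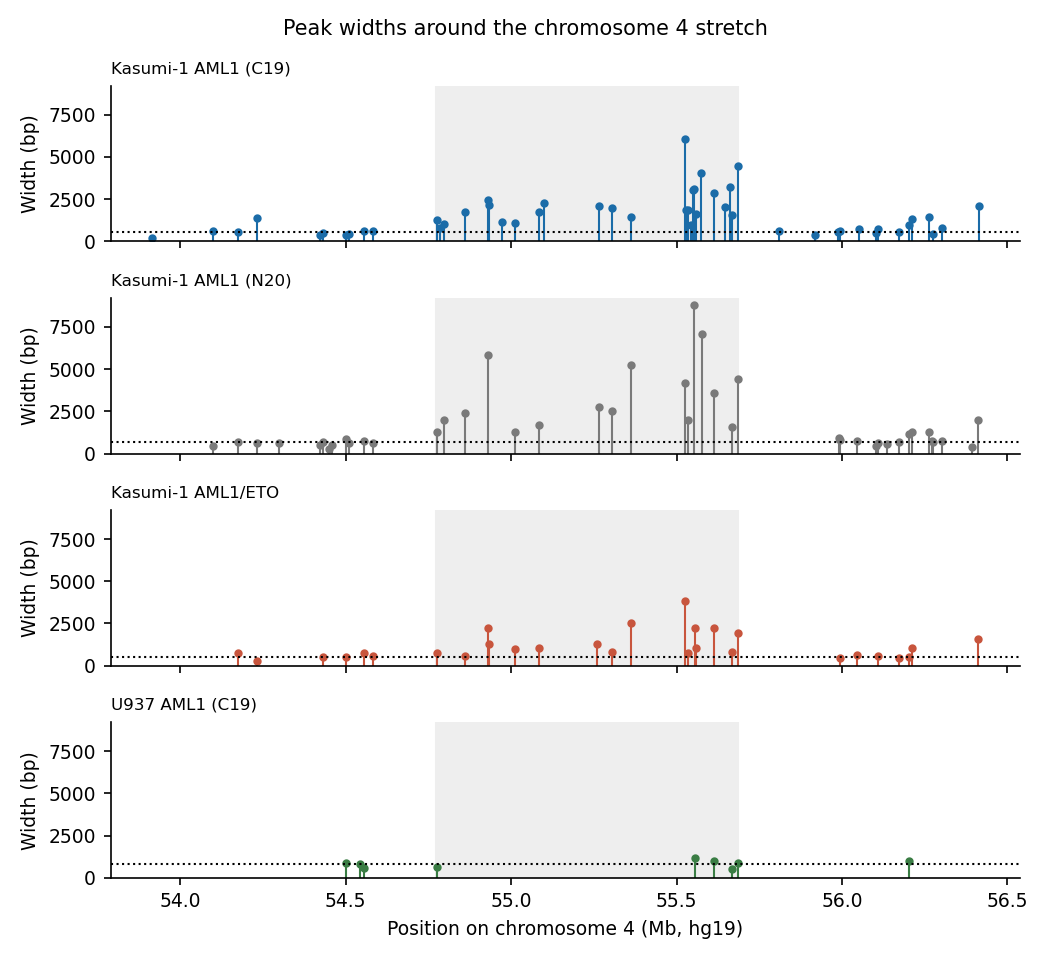
Width of each peak (y axis, bp) against its centre on chromosome 4 (x axis, Mb, hg19) in the 4 lists, with the median width of each whole list as a dotted line and the stretch from 54774554 to 55686558 shaded. Median widths in the shaded part are 1901 bp for C19, 2621 bp for N20 and 1161 bp for AML1/ETO, and 884 bp for U937.

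The densest 1 Mb window was a different one in each list. C19 peaks were densest at chromosome 17 from 73 to 74 Mb, with 54 peaks, of which 26 overlapped an AML1/ETO peak and 3 a U937 peak. N20 peaks were densest at chromosome 11 from 65 to 66 Mb, with 50 peaks, of which 34 overlapped a C19 peak and 34 an AML1/ETO peak. AML1/ETO peaks were densest at chromosome 9 from 130 to 131 Mb, with 40 peaks, of which 28 overlapped a C19 peak, 37 an N20 peak and 5 a U937 peak. A window at chromosome 15 from 75 to 76 Mb held 38 AML1/ETO peaks, all of them on an N20 peak, 31 on a C19 peak and 14 on a U937 peak. U937 peaks were densest at chromosome 18 from 60 to 61 Mb, where 46 peaks stood against 14 C19 peaks in Kasumi-1, and 5 of the 46 overlapped a C19 peak. The next densest U937 window, at chromosome 15 from 70 to 71 Mb, held 30 U937 peaks and 34 C19 peaks, and 19 of the 30 overlapped a C19 peak.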

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

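The 50% overlap and the removal of chromosome X were chosen before the data were examined, as was the centre distance of 250 bp. The 3000 widest peaks, the width standardisation, the N20 restriction, the moved-peak chance level and the removal of the chromosome 4 stretch were chosen after. The difference in U937 overlap between AML1 peaks with and without AML1/ETO stayed positive under each alternative it was computed for. Asking for 50% of the shorter peak moved none of the 8 shares and differences it could be applied to beyond their counting intervals. Leaving out chromosome X or the chromosome 4 stretch moved none of 9. The stretch held 26 of the 24154 C19 peaks and 16 of the 15374 AML1/ETO peaks. These are too few to move a share beyond its interval, so its removal was no test of the shares. With centres within 250 bp, AML1/ETO overlapped C19 in 70.9% and N20 in 84.7% of peaks. C19 overlapped AML1/ETO in 45.1%, N20 in 59.6% and U937 in 16.8%, and U937 overlapped C19 in 41.3% and AML1/ETO in 33.1%. The difference in U937 overlap between AML1 peaks with and without AML1/ETO was then 15.8 points. With the 3000 widest peaks of every list, AML1/ETO and C19 overlapped in 46.9% of either list. N20 covered 64.2% of AML1/ETO and 47.7% of C19 peaks. U937 overlapped C19 in 19.1% and AML1/ETO in 23.1%, which reverses their order from 46.6% and 37.8% in the full lists. The full C19 list is the longer one, and relative to random placement U937 already overlapped AML1/ETO more, at 45.7 against 35.8 times chance. With moved peaks these folds were 17.5 and 16.1, and under both placements their ranges over the draws overlapped. With lists of equal length, the share of AML1/ETO peaks on AML1 no longer exceeded that of AML1 peaks on AML1/ETO, because such lists share about equal numbers. Shorter lists leave fewer peaks to overlap by construction. The width correlation was 0.47 in these peaks, and the cause was not tested. Choosing peaks by width narrows the range of both widths, which can by itself lower a correlation. The difference in U937 overlap was 17.4 points after standardising over width deciles and 14.4 points among N20-supported AML1 peaks, and the cause of these shifts was not tested. Of 8 further shares, centres within 250 bp lowered 7 and raised 1 beyond their intervals, and the 3000 widest peaks lowered 4 and raised 2. Moving peaks by 5 to 50 kb lowered the fold over chance of all 12 overlaps, to between 14.0 and 23.1. The lists give no depth, so a site missing from one list is not shown to be unbound, and list length may reflect depth or threshold as much as binding. Not run were the alternatives that need peak scores (p of 1e-10, the 3000 highest-scoring peaks, N20 at 1e-8) and those on motif windows, promoter distance and gene lists. The width correlation was not recomputed under the other overlap definitions. No paired analysis was possible because each antibody and cell line had 1 library.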

Other observations

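The difference in U937 overlap was planned before the data were examined, and the test of AML1/ETO peaks against C19 peaks within 1 kb was set before its result was seen; the other tests of explanations in this part were chosen only after the results were seen.

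The chromosomes held different shares of the AML1 peaks of the 2 cell lines. Chromosome 18 had 3.22% of the U937 peaks and 1.97% of the Kasumi-1 C19 peaks, the largest ratio at 1.63, and chromosome 22 had 1.20% and 2.13%, the smallest at 0.564. Chromosome 17 had 3.51% and 5.82%. The share of U937 peaks on a Kasumi-1 C19 peak went from 31.3% on chromosome 18 to 60.3% on chromosome 19. Within Kasumi-1 the share of AML1/ETO peaks on a C19 peak varied less, from 69.0% on chromosome X to 80.3% on chromosome 3, and that of C19 peaks on AML1/ETO from 42.4% on chromosome X to 55.4% on chromosome 22. In the U937 window with the most peaks, at chromosome 18 from 60 to 61 Mb, 34 of 46 peaks were wider than the U937 median, and the median width was 1016 bp against 802 bp.

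Kasumi-1 peaks were wide along 1 stretch of chromosome 4, from 54774554 to 55686558 (912 kb). It was the longest of 13 C19 stretches of 250 kb windows with a median peak width above 2 times the list median, and its 26 C19 peaks had a median width 3.46 times that of the list. An error of mapping or assembly common to human libraries is argued against by U937, whose widest peak in the stretch was 1.49 times the U937 median, although this rests on 5 peaks. A candidate explanation is a gain in copies of this stretch in Kasumi-1. In it, 32 of the 32 N20 and AML1/ETO peaks, or 100% (89.3 to 100), were wider than their list median. Widths at shared sites are correlated between the lists, however, and the stretch was set from wide C19 peaks. Over the genome 94.6% of AML1/ETO peaks overlapped an N20 peak, so the 32 are not independent and the interval is too narrow. A dense domain of strong binding in Kasumi-1 could give such widths too. It stays open as well, since copy number was not measured here. Both chromosome 4 sites named in the results lie in this stretch.

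AML1 sites with AML1/ETO were found again in U937 more often than AML1 sites without it, by 18.6 percentage points. Peak width is argued against as the whole cause. The difference stayed at 17.4 points (16.3 to 18.4) when standardised over deciles of AML1 peak width. Stronger peaks being found again more often stays open, because width is only a stand-in for strength. Among AML1 peaks without AML1/ETO, U937 overlap did not rise with width, at 10.9% in the narrowest quartile and 9.32% in the widest. C19 peaks that N20 does not find are argued against as the whole cause too, since 14.4 points (13.0 to 15.7) remained among peaks that N20 also found. Unspecific peaks that both antibodies recover pass this filter and stay open. N20 support at peaks with AML1/ETO can also come from the fusion protein. Open chromatin that any antibody recovers stays open: among N20 peaks without C19, those with AML1/ETO overlapped U937 more often by 4.80 points (3.38 to 6.26), which was 9.56 points (7.61 to 11.5) less than among C19 peaks with N20. Among merged sites, overlap with U937 was 7.93% for C19 alone, 15.5% for C19 with N20 and 14.7% for C19 with AML1/ETO. It was 29.7% where all 3 antibodies marked the site. A similar rise over C19 alone thus came with either N20 or AML1/ETO, so that rise was not particular to AML1/ETO. The share for C19 with AML1/ETO rests on 265 sites (10.96 to 19.49). Where N20 was present, sites with AML1/ETO overlapped U937 more often, at 29.7% against 15.5%. N20 detects both proteins, so it is not an unrelated comparison. A preference of the fusion protein for sites that AML1 binds in both cell lines was not tested and stays open.

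AML1/ETO peaks without a C19 peak made up 24.2% of the AML1/ETO list. A displaced or split C19 peak beside them is argued against for most of them, since 7.75% (6.94 to 8.66) had a C19 peak centre within 1 kb. AML1 bound below the C19 threshold stays open: the share without C19 was 6.70% (5.55 to 8.06) in the widest decile of AML1/ETO peaks and 39.4% in the narrowest, but the C19 signal at these sites was not analysed here. Binding by the fusion protein without AML1 is the biological alternative and cannot be told apart from it with peak positions alone.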
